A study of Mus musculus with 9 samples.

How the data were processed

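PRO-seq libraries of the mouse erythroid lines G1E and G1E-ER4 were taken as deposited. The 9 libraries form 4 groups, which are G1E (n = 2) and G1E-ER4 at 0 h (n = 3), 13 h (n = 2) and 24 h (n = 2) of 100 nM estradiol. The labels do not say that replicates came from separate cultures, so the p-values of tests between groups measure only the spread between these libraries.

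The deposited gene-body table holds raw read counts for 24391 genes in each library, per the file headers. The deposited table of dREG peaks holds raw read counts for 26991 regions of polymerase initiation, per the file headers. It lists 42114 entries, of which 11718 are whole peaks and 30396 are single strands of a peak, and each entry is called an element here. The submitters' processing notes name the aligner BWA and the build mm9. The aligner's version, the counting tool and the gene annotation behind the deposited counts are not given in the sources used here. Whether the gene-body counts use strand is not stated either, so genes that overlap or lie antisense to another gene are uncertain, and so are near-identical copies such as Hbb-b1 with Hbb-bs, Hbb-b2 with Hbb-bt, and Csf2rb with Csf2rb2. The authors' peak table also gives a p-value per element from a test over groups that are not stated, which was not used. It gives each peak's position along an overlapped gene as a percent, as deposited, together with the authors' cluster, a mark for regulatory elements, a location class and the names of neighbouring genes.

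Total gene-body counts ran from 37830789 to 139945759 per library, and total element counts from 15394427 to 59952454. These totals limit the precision of every value, and counting intervals cover counting error only, since PCR copies were not removed by molecular identifiers in these counts. No reference of build mm9 was at hand, so coordinates are those of the deposited peak table, in mm9. Gene starts were taken from peaks that the authors placed at a start. The table lists 17895 starts, 14798 of them name 1 gene, and after 41 genes with a chromosome mismatch were dropped a start was known for 10996 tested genes. Gene ends were unknown.

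Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter, 4 group means and the robust quasi-likelihood test, which left 5 residual degrees of freedom. The filter kept 13825 genes and 35158 elements. The p-values were adjusted with Benjamini-Hochberg over all genes, or all elements, of a comparison, and the threshold was 0.05. Scaled counts (CPM) use TMM and given as mean ± SD. Each fold change is given on the log2 scale with a standard error (SE). The quasi-likelihood test gives no SE, so it was derived as the absolute fold change over the square root of the F statistic. Where a group held 0 reads, the fold is a lower bound against 3 reads over the group. Where it held 1 to 3 reads, the ratio is given with its 95% counting interval. The 4 comparisons were 13 h with 0 h, 24 h with 0 h, 24 h with 13 h, and G1E-ER4 at 0 h with G1E.

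The 18 gene lists were alpha and beta globin genes, haem synthesis, red cell membrane and cytoskeleton, iron uptake and storage, erythroid transcription factors, stem and progenitor regulators, S phase and DNA replication, mitosis, ribosome biogenesis, autophagy and organelle clearance, megakaryocyte markers, mast cell and basophil markers, granulocyte and monocyte markers, lymphocyte markers, textbook oestrogen receptor targets, immediate early genes, heat shock and stress response, and housekeeping genes. They hold 296 genes. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. The lists, the comparisons, the tests, the rule for named genes and most alternatives were fixed before the data were examined.

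Named genes follow a rule. For each comparison it takes the 10 largest increases and the 10 largest decreases among called genes with a mean count of at least 50, no overlap of the groups' CPM and a name that is not a predicted or clone name. It adds up to 4 genes per list, and always Gata1, Gata2, Kit, Myc, Myb, Klf1, Alas2, Slc4a1, Hba-a1, Hbb-b1, Zfpm1 and Tal1. For elements it takes the 5 largest changes each way, every called element within 100 kb of the starts of Kit, Gata2 or Myc, and the 10 transient elements with the largest increase. Some genes that the rule names are not reported here.

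A gene or element was called activated at 13 h where it rose by at least 1 on the log2 scale past the test. It was called transient where it was activated and then fell past the test, by any size, between 13 h and 24 h. An element was distal where it lay over 1 kb from every listed start. A gene counted as near an element where the gap between the element and the gene's start was at most 100 kb or the element lay inside the gene, because gene ends were unknown. Shares of genes near an activated distal element were set against 10000 draws of control genes, not called at 24 h, matched on expression and on the number of elements around them. The share of the 24 h fall reached at 13 h was compared between genes with and without such an element by a two-sided permutation test with 100000 resamples. Neighbouring genes were compared between the lines in windows of 10 Mb with at least 15 genes of mean CPM 5 or more. Fold changes were taken relative to the median of all these genes, and a window counted as shifted where its median passed 0.2 either way. This window comparison was added after the differences between the lines were seen.

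The library titles carry numbers that fall into 4 runs. Run 1 holds 0 h replicate 1 and 13 h replicate 1, run 2 holds 0 h replicate 2 and 13 h replicate 2, run 3 holds G1E replicate 1, 0 h replicate 3 and both 24 h libraries, and run 4 holds G1E replicate 2. The labels do not call these runs batches. The 13 h and 24 h libraries lie in different runs, so that comparison was also fitted with the run as a block, which leaves 2 residual degrees of freedom. Fold changes taken from part of the libraries, as within a run or between pairs of libraries, are differences of log2 values with 0.1 CPM added.

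Alternatives were DESeq2 1.42.0 size factors and its own test, total counts, no filter, 2 groups in the fit, gene-body scaling for elements, a block by title number or by replicate number, a fold threshold of 2, other windows around genes, and leaving out each library in turn. Tables and tests were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

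The calls and the list test were tried on counts simulated from the 0 h levels with the sizes of the real libraries, with changes planted at 13 h and 24 h against 0 h. None was planted between 13 h and 24 h or between the lines, and the comparison of windows was not tried in this way. For 13 h against 0 h, 38 of 100 genes changed 2-fold and 79 of 100 changed 4-fold were recovered among 13043 simulated genes, with 7 calls among 12853 unchanged genes. For 24 h against 0 h the numbers were 52 and 82 of 100, with 8 such calls. For elements, 8 of 100 2-fold and 48 of 100 4-fold changes were recovered at 13 h among 31822 simulated elements, and 7 and 52 of 100 at 24 h. At 13 h a planted gene list was called and 0 of 20 random lists were. Marks of a nearby activated element, drawn at random for each gene, gave 0 of 20 results past the threshold in the tests of nearby genes and of the share of the fall. Neighbouring genes did not share these marks as they share real elements, so the effect of that sharing on the p-values was not tried.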

Results

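PRO-seq, which reads nascent RNA still held by engaged RNA polymerase, was measured in 9 libraries of mouse erythroid cells. G1E is a red cell progenitor line that lacks working GATA1, the master transcription factor of red cell maturation. G1E-ER4 is its derivative with GATA1 fused to the ligand-binding part of the oestrogen receptor, so that estradiol switches GATA1 on and the cells mature. The groups were G1E (n = 2) and G1E-ER4 after 0 h (n = 3), 13 h (n = 2) and 24 h (n = 2) in 100 nM estradiol. Gene-body reads summed to 96043832 and 37830789 in G1E replicates 1 and 2, to 70703867, 71438653 and 139945759 in the 3 libraries of 0 h, to 73290342 and 84779260 at 13 h, and to 90192788 and 97942959 at 24 h. Reads in dREG peaks, the regions where polymerase initiates at promoters and enhancers, summed to between 15394427 in G1E replicate 2 and 59952454 in 0 h replicate 3. Rn45s, the ribosomal RNA precursor, took the most gene-body reads in each library, between 1.63% and 6.79%. Across the libraries, the first principal component of gene-body signal carried 61.6% of the variance and ran from G1E over 0 h and 13 h to 24 h.

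Values after gene names are edgeR's log2 fold changes ± the SE derived from its F statistic, with the n of each group as above. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and levels are scaled counts (CPM) ± SD. Gata1 itself was read at 214 and 165 CPM in the G1E libraries, at 257, 188 and 198 CPM at 0 h, at 280.1 and 214 CPM at 13 h, and at 301 and 301 CPM at 24 h. The labels do not say which part of Gata1 is disrupted and gene-body reads cover the whole gene, so these levels check no label. Esr1, whose hormone-binding part the fusion carries, separated the lines at 0.671 ± 0.198 CPM in G1E against 17.5 ± 9.99, 17.5 ± 7.51 and 25.5 ± 6.69 CPM in G1E-ER4 at 0 h, 13 h and 24 h.

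The comparison of 13 h with 0 h asks what had changed midway through the course. Alas2 and other genes of red cells had risen, and some mast cell and progenitor genes had fallen. Alas2, the first enzyme of haem synthesis in red cells (start at chromosome X, 146981960, mm9), rose 148-fold, from 0.903 ± 0.330 CPM (n = 3) to 132 ± 56.5 CPM (n = 2; 7.21 ± 0.51, edgeR adjusted p = 8.80e-06). Cpa3, a mast cell protease, fell 312-fold, from 53.5 ± 21.8 to 0.171 ± 0.0269 CPM (-8.29 ± 0.54). Gata2, the GATA factor of progenitors that GATA1 replaces, fell from 154 ± 27.9 to 28.7 ± 11.2 CPM (-2.42 ± 0.48), and Kit, the stem cell factor receptor, fell from 562 ± 76.5 to 248 ± 69.2 CPM (-1.18 ± 0.32). In all, 2782 genes rose and 2888 fell among 13825 tested.

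The largest increases at 13 h included genes that were close to silent at 0 h. Slc52a3, a riboflavin transporter (start at chromosome 2, 151825602, mm9), rose 939-fold from 0.0588 ± 0.00625 to 57.2 ± 0.761 CPM (9.88 ± 0.36). Ptk6, a cytoplasmic tyrosine kinase, rose by 9.53 ± 0.44. Olfm2 (8.11 ± 0.58), Btnl10 (7.70 ± 0.69), Cpne6 (7.37 ± 0.61) and Dok7 (7.25 ± 0.60) followed. The amino acid transporter Slc38a5 (7.25 ± 0.31), the transcription factor Nrl (7.25 ± 0.58) and the mitochondrial enzyme Acsf3 (6.98 ± 0.67) also rose. Among the largest decreases, Ceacam3 held 0 reads at 13 h and was at least 80.7-fold lower, and Myct1 held 0 reads and was at least 30.3-fold lower. Vmn2r97 was 345-fold lower (95% counting interval 61.9 to 13620.0), and Dnah7b 113-fold lower (38.5 to 545). Ms4a2, a chain of the IgE receptor, fell (-6.59 ± 0.84), as did Lrrc66 (-6.59 ± 0.64), the steroid enzyme Cyp11a1 (-6.28 ± 0.61), Nhsl2 (-6.12 ± 0.38) and Tespa1 (-5.67 ± 0.63).

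Among the fixed lists, each of the 6 tested globin genes rose at 13 h, among them Hbb-b2 (4.81 ± 0.67) and Hbb-b1 (3.80 ± 0.78), whose copies share reads. Camera gave the list an adjusted p = 0.0008995, and adjusted p = 0.252 with an estimated correlation. The 6 genes include the copies Hbb-bs and Hbb-bt, so they are not 6 separate measurements. The preset correlation takes no account of that, here or in the other comparisons. Hba-a1 and Hba-a2 held 0 reads in every library, so the alpha chain could not be measured. Of 14 haem synthesis genes 10 rose and 0 fell, including the mitochondrial transporters Abcb10 (3.72 ± 0.16) and Tmem14c (2.51 ± 0.16) and the enzyme Ppox (2.17 ± 0.30), with camera adjusted p = 4.23e-09, and adjusted p = 0.252 with an estimated correlation. In the red cell membrane and cytoskeleton list 12 of 19 rose and 0 fell. There, the cytoskeletal proteins Dmtn (5.55 ± 0.20) and Sptb (3.68 ± 0.20) were among those that rose, with camera adjusted p = 4.79e-08, and adjusted p = 0.252 with an estimated correlation. Of 18 autophagy and organelle clearance genes 10 rose and 0 fell, such as Pink1 (2.21 ± 0.38) and Wipi1 (1.95 ± 0.27), with camera adjusted p = 0.00623, and adjusted p = 0.252 with an estimated correlation.

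Of 23 ribosome biogenesis genes 17 fell at 13 h and 0 rose, such as Polr1b (-1.63 ± 0.19), Wdr12 (-1.57 ± 0.30) and nucleolin, Ncl (-1.33 ± 0.14). Camera gave adjusted p = 3.49e-07, and adjusted p = 0.454 with an estimated correlation. Of 15 stem and progenitor regulators 5 fell, namely Kit, Gata2, Myb (-2.34 ± 0.60), Lyl1 (-4.62 ± 0.21) and Etv6 (-1.37 ± 0.21), and Fli1 rose (1.17 ± 0.38). That list had camera adjusted p = 0.02, and adjusted p = 0.532 with an estimated correlation, 0.0531 without 13 h replicate 2 and 0.0632 without G1E replicate 2. Myc, the growth regulator, had -0.45 ± 0.30 (edgeR adjusted p = 0.260) and did not pass the test. Of 9 mast cell and basophil markers 5 fell, among them Cpa3, Ms4a2 and Il1rl1 (-3.66 ± 0.54), and the granule proteoglycan Srgn rose, with camera adjusted p = 0.0144, and adjusted p = 0.454 with an estimated correlation.

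Erythroid transcription factors moved both ways at 13 h, with 5 of 15 higher and 6 lower (camera adjusted p = 0.6996). Klf1 (0.92 ± 0.20), the GATA1 partner Zfpm1 (2.92 ± 0.35) and Lmo2 (1.24 ± 0.23) rose, and Sox6 (-2.69 ± 0.17), Bcl11a (-2.00 ± 0.32) and Tal1 (-0.56 ± 0.15) fell. In iron uptake and storage 3 of 13 rose, including the transferrin receptor Tfrc (1.53 ± 0.17), and 3 fell, including Tfr2 (-2.50 ± 0.22), with camera adjusted p = 0.976. In mitosis 9 of 19 rose, such as Tpx2 (1.66 ± 0.22) and Nusap1 (1.53 ± 0.18), and Cdk1 fell (-0.39 ± 0.12), with camera adjusted p = 0.00948, and adjusted p = 0.599 with an estimated correlation. In S phase and DNA replication 3 of 22 rose, among them Ccne1 (1.11 ± 0.22) and Cdc6 (1.14 ± 0.15), and 3 fell (camera adjusted p = 0.901). Of 12 megakaryocyte markers 3 rose, namely Itgb3 (2.58 ± 0.33), Gp1ba (2.04 ± 0.42) and Tubb1 (3.41 ± 0.42), and 2 fell (camera adjusted p = 0.469). Adjusted over the list alone, 1 haem gene fell, 13 membrane genes rose, 11 autophagy genes rose and 1 fell, 18 ribosome biogenesis genes fell, 2 S phase genes rose and 1 fell, and 4 megakaryocyte markers rose. The counts of the other lists named here were the same.

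At elements, 5358 of 35158 rose at 13 h and 6524 fell. Which direction has more depends on the setting, with 5626 up and 4428 down under gene-body scaling and 5848 up and 5597 down without G1E replicate 2. Those at gene starts rose more often than they fell, 2073 against 1739 of 12973, and intergenic ones fell more often, 2404 against 1300 of 10044. The largest increases lay at the starts of Slc52a3 (chromosome 2, 151821950 to 151829351, mm9; 9.19 ± 0.32), Gng13 (chromosome 17, 25851850 to 25854801; 8.81 ± 0.62), Ptk6 (chromosome 2, 180935500 to 180938551; 8.43 ± 0.55) and Alas2 (chromosome X, 146981250 to 146984301; 8.17 ± 0.62), and at an intergenic peak between Iqsec1 and Nup210 (chromosome 6, 90955600 to 90960001; 8.20 ± 0.44). Elements inside Cyp11a1 (chromosome 9, 57869150 to 57870151) and Auts2 (chromosome 5, 132744600 to 132746651) went from 4.68 ± 1.14 and 3.82 ± 0.718 CPM to 0. Elements inside Lrp1b, Arhgap12 and Luzp2 went to 0 as well, from 3.37 ± 1.85, 2.24 ± 1.11 and 2.14 ± 0.445 CPM.

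Without 13 h replicate 1 the genes that fell were 1709 and the called elements 7625, and the calls of Kit (adjusted p = 0.126 in edgeR), Myb (0.0774) and Tal1 (0.102) were lost. Without 13 h replicate 2, Myb (edgeR adjusted p = 0.0509) and Tal1 (0.0595) were not called either, and with a block by replicate number Kit (0.0538) and Tal1 (0.0506) were not. The calls of Kit (0.0932), Myb (0.106) and Myct1 (0.0908) were also lost without the expression filter.

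**Figure D1:**
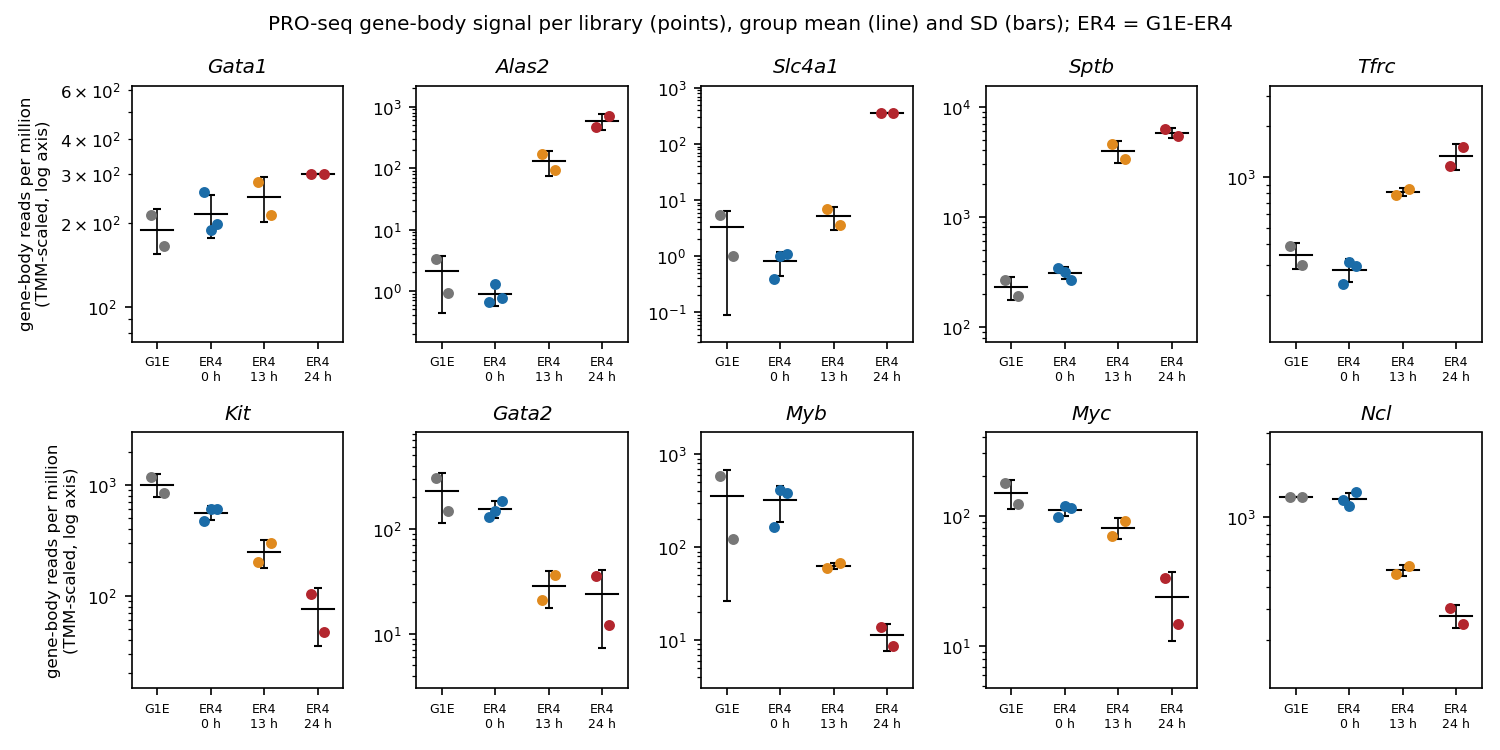
Gene-body CPM on a log axis for 10 genes in each library (points), with the group mean (line) and SD (bars) for G1E and for G1E-ER4, written ER4, at 0 h, 13 h and 24 h. Alas2 went from 0.903 to 132 and 582 CPM and Slc4a1 from 0.821 to 5.26 and 354 CPM, and Myb went from 319 to 63.2 and 11.3 CPM.

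At 24 h the comparison with 0 h asks what the cells had become at the end of the course. Slc4a1 and Alas2 were far above their 0 h levels, and Kit, Myb and Myc were below theirs. Slc4a1, the band 3 anion exchanger and the main membrane protein of red cells (start at chromosome 11, 102226595, mm9), rose 422-fold, from 0.821 ± 0.376 to 354 ± 1.88 CPM (n = 2; 8.72 ± 0.67, edgeR adjusted p = 3.93e-06). Alas2 rose 649.9-fold to 582 ± 166 CPM (9.34 ± 0.55). Kit fell from 562 ± 76.5 to 75.8 ± 40.8 CPM (-2.89 ± 0.35), Myb from 319 ± 134 to 11.3 ± 3.67 CPM (-4.82 ± 0.69) and Myc from 109.7 ± 10.9 to 24.0 ± 13.0 CPM (-2.19 ± 0.32). In all, 4014 genes rose and 4246 fell.

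The largest increases at 24 h were Slc52a3 (10.91 ± 0.37), Ptk6 (9.78 ± 0.45), Alas2, Slc4a1, Slc38a5 (8.33 ± 0.32), Btnl10 (7.92 ± 0.69), Nrl (7.77 ± 0.58), Olfm2 (7.62 ± 0.57), the cytokine receptor gene Csf2rb2 (7.52 ± 0.22), which has the near copy Csf2rb, and Hbb-b1 (7.30 ± 0.80). Among the largest decreases Fzd9 held 0 reads at 24 h and was at least 190.5-fold lower, Ms4a2 at least 165.0-fold, Clec4e at least 131-fold and Ceacam3 at least 78.6-fold. Cpa3 (-10.38 ± 0.64), the matrix protease Adamts5 (-9.21 ± 0.42), Cyp11a1 (-8.98 ± 0.75), Sel1l3 (-8.35 ± 0.48), Rgs14 (-8.22 ± 0.43) and Pgpep1l (-7.88 ± 0.56) fell as well.

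Each of the 6 tested globin genes, copies included, rose at 24 h, among them Hbb-b2 (6.48 ± 0.69). Camera gave adjusted p = 0.000566, and adjusted p = 0.255 with an estimated correlation. Of 14 haem synthesis genes 13 rose, such as Abcb10 (4.48 ± 0.17), the iron importer Slc25a37 (3.34 ± 0.15) and Fech (2.48 ± 0.22), which inserts iron into haem, with camera adjusted p = 1.24e-09, and adjusted p = 0.255 with an estimated correlation. In the membrane list 16 of 19 rose, among them Dmtn (6.72 ± 0.21) and Sptb (4.24 ± 0.20), with camera adjusted p = 2.35e-09, and adjusted p = 0.255 with an estimated correlation. In autophagy and organelle clearance 14 of 18 rose, including Bnip3l (1.20 ± 0.18), which removes mitochondria, and Wipi1 (3.25 ± 0.28), and Trim58 fell (-3.50 ± 0.69), with camera adjusted p = 0.000712, and adjusted p = 0.255 with an estimated correlation. In mitosis 12 of 19 rose, such as Nusap1 (2.35 ± 0.18) and Ccna2 (1.68 ± 0.16), and Cdk1 fell (-0.84 ± 0.13), with camera adjusted p = 0.0135, and adjusted p = 0.5995 with an estimated correlation.

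All 23 ribosome biogenesis genes fell at 24 h, such as Mybbp1a (-3.04 ± 0.23), Polr1a (-3.07 ± 0.46) and Ncl (-2.19 ± 0.14). Their median was -2.40, with camera adjusted p = 2.29e-12, and adjusted p = 0.255 with an estimated correlation. In S phase and DNA replication 18 of 22 fell, including Cdt1 (-2.79 ± 0.32), Uhrf1 (-2.56 ± 0.24), Pcna (-2.19 ± 0.24) and Mcm6 (-1.86 ± 0.19), and Ccne1 (1.24 ± 0.22) and Cdc6 (1.06 ± 0.15) rose. That list had camera adjusted p = 0.000125, and adjusted p = 0.367 with an estimated correlation. Of 15 stem and progenitor regulators 9 fell, among them Kit, Myb, Gata2 (-2.70 ± 0.49), Lyl1 (-5.46 ± 0.22) and Erg (-3.86 ± 0.64), and Fli1 rose (1.06 ± 0.38), with camera adjusted p = 0.00243, and adjusted p = 0.367 with an estimated correlation. Of 9 mast cell and basophil markers 6 fell, including Il1rl1 (-7.08 ± 0.67), and Srgn rose, with camera adjusted p = 0.0294, and adjusted p = 0.469 with an estimated correlation, 0.19 without 24 h replicate 2 and 0.0572 under total counts.

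Of 15 erythroid transcription factors 7 rose at 24 h and 3 fell (camera adjusted p = 0.642). Zfpm1 (3.33 ± 0.36), Nfe2 (1.80 ± 0.24), Klf3 (1.14 ± 0.13), Klf1 (0.98 ± 0.20) and Gata1 (0.49 ± 0.18, edgeR adjusted p = 0.0349) were among those that rose, and Sox6 (-3.04 ± 0.17) and Bcl11a (-2.63 ± 0.34) fell. Tal1 had 0.03 ± 0.15 and did not pass the test. In iron uptake and storage 4 of 13 rose, led by the ferritin receptor Ncoa4 (2.55 ± 0.29) and Tfrc (2.24 ± 0.17), and 2 fell, including Tfr2 (-3.26 ± 0.23), with camera adjusted p = 0.651. Of 12 megakaryocyte markers 3 rose, such as Tubb1 (4.85 ± 0.44), and 3 fell, such as Nbeal2 (-2.06 ± 0.28), with camera adjusted p = 0.838. Adjusted over the list alone, 13 mitosis genes rose and 1 membrane gene fell, and the other counts of these lists were the same.

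At elements, 7984 rose at 24 h and 10386 fell, but without 24 h replicate 2 there were 6904 that rose and 6652 that fell. Of the intergenic ones 40.3% fell and of those at gene starts 30.0% rose. Besides the starts of Slc52a3 (10.16 ± 0.33) and Alas2 (9.64 ± 0.63), the largest increases were intergenic, near Arhgdib (chromosome 6, 136894750 to 136895351, mm9; 8.66 ± 0.37), between Ankrd6 and Rragd (chromosome 4, 33056500 to 33057601; 9.73 ± 1.11) and between Cks2 and Shc3 (chromosome 13, 51723500 to 51725201; 8.44 ± 0.83). Elements at Olfr1509, near Klhl1, between Akap7 and Arg1, in Grm4 and in Nhsl2 went from 8.04 ± 1.07, 7.39 ± 0.727, 7.33 ± 2.61, 6.11 ± 2.24 and 5.48 ± 1.72 CPM to 0.

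Scaling by total counts moved the median over all tested genes from -0.07 to -0.45, which left 2614 genes higher and 5863 lower, and Gata1 at 0.09 was then not called (edgeR adjusted p = 0.677). Gata1 was also not called without 0 h replicate 2 (0.109), 0 h replicate 3 (0.102), 24 h replicate 1 (0.1) or 24 h replicate 2 (0.101).

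**Figure D2:**
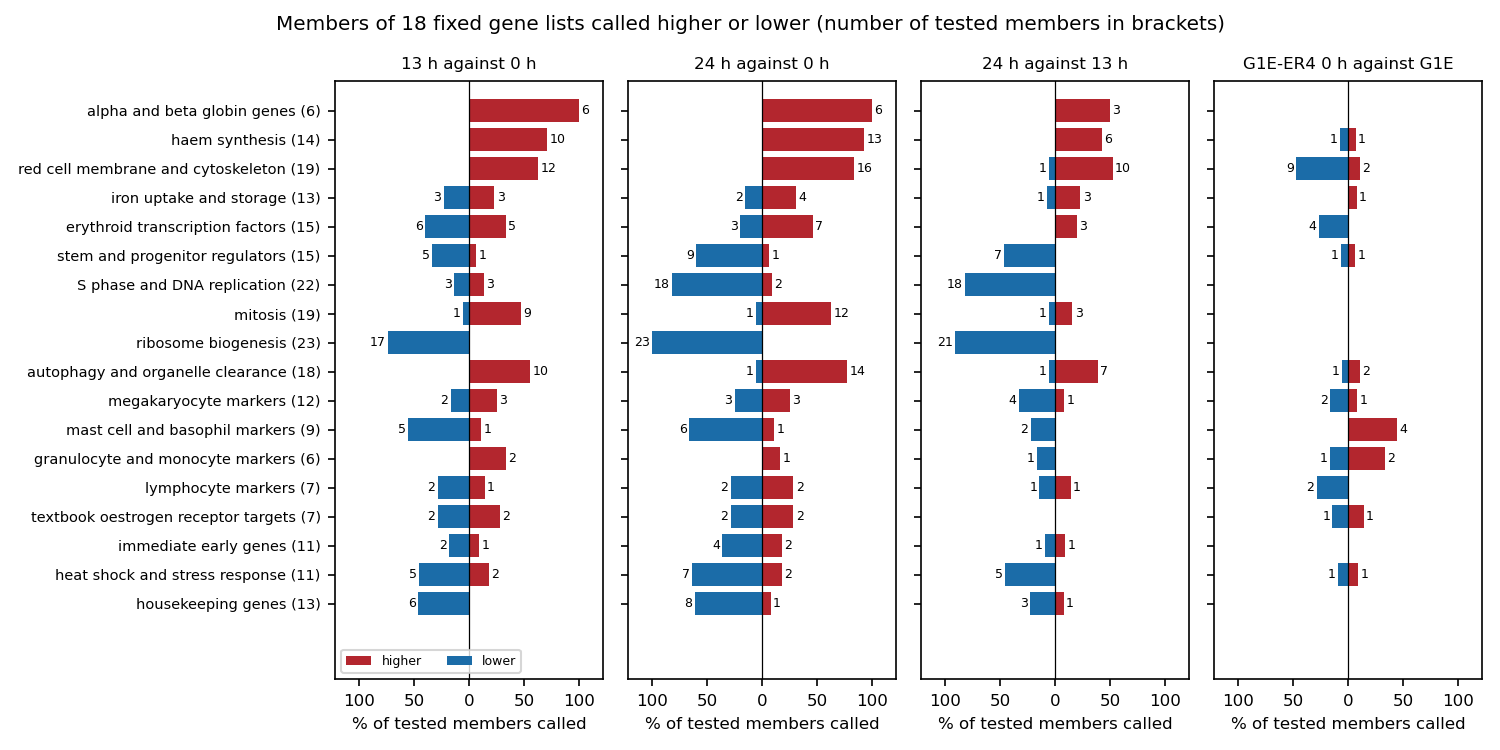
Percent of the tested members of 18 gene lists called higher (red, right) or lower (blue, left) in each of 4 comparisons, with the number of called members at each bar. All 23 ribosome biogenesis genes were lower at 24 h than at 0 h, and 18 of 22 S phase genes were lower at 24 h than at 13 h.

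Both time points shared most of their direction. Among tested genes 2423 were higher at both 13 h and 24 h than at 0 h and 2583 were lower at both, where independent lists of these sizes would share 807.7 and 887.0. Another 1581 rose and 1648 fell at 24 h alone past the test, and the 13 h value of those that fell had a median of -0.38. Among elements 4210 were higher and 5809 lower at both times, against 1217 and 1927. Both comparisons use the same 0 h libraries, whose 3 libraries cannot be split into parts of 2, so part of the excess may come from them. Across genes, which are not independent replicates, the fold changes at 13 h and 24 h had r = 0.858 and covariance 1.85, and unchanged simulated groups against the same controls gave 0.383 and 0.0491.

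Between 13 h and 24 h the comparison asks what changed in the later part of the course. Slc4a1 rose 67.5-fold (6.08 ± 0.71, edgeR adjusted p = 0.00124) and Spry4, an inhibitor of growth factor signalling, fell 30.4-fold, from 14.8 ± 5.13 to 0.484 ± 0.0541 CPM (-4.93 ± 0.32, adjusted p = 0.000142). Cdt1, which licenses DNA replication (-2.11 ± 0.32), and the ribosome biogenesis factor Nop56 (-1.74 ± 0.25) fell. Kit fell further (-1.71 ± 0.34) and Myc fell (-1.75 ± 0.33), while Gata2 was level (-0.27 ± 0.48, adjusted p = 0.711) after its earlier fall. With a block for the run of title numbers Spry4 kept its call, and Slc4a1 (edgeR adjusted p = 0.0514), Cdt1 (0.0787), Nop56 (0.123), Kit (0.112) and Myc (0.119) lost theirs. In all, 1617 genes rose and 1732 fell, a balance that depends on the scaling, since total counts gave 641 and 3082. At a fold threshold of 2 there were 403 and 1084.

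Besides Slc4a1, the largest increases between 13 h and 24 h were Htr1f (3.65 ± 0.62), Hspa12a (3.52 ± 0.72), the beta globin copies Hbb-bs and Hbb-b1 (3.50 ± 0.75 and 3.50 ± 0.75), Rragd (3.06 ± 0.39), a GTPase of nutrient sensing, Dpep1 (2.95 ± 0.61), Ltb4r1 (2.82 ± 0.47), Psma8 (2.71 ± 0.53) and Kcng3 (2.53 ± 0.62). Besides Spry4, the decreases were led by Fzd9, at least 10.4-fold lower with 0 reads at 24 h, Etv4 (-4.55 ± 0.74), Pgpep1l (-4.47 ± 0.51), Erv3 (-4.42 ± 0.78), the growth factors Fgf3 (-4.18 ± 0.85) and Fgf15 (-3.90 ± 0.64), Lhfp (-3.90 ± 0.52), Adamts5 (-3.86 ± 0.45) and Plk3 (-3.78 ± 0.40).

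In S phase and DNA replication 18 of 22 fell between 13 h and 24 h and 0 rose, with a median of -1.14, camera adjusted p = 2.26e-14, and adjusted p = 0.331 with an estimated correlation. In ribosome biogenesis 21 of 23 fell, such as Rrp9 (-1.81 ± 0.26) and Mybbp1a (-1.64 ± 0.23), with camera adjusted p = 4.72e-14, and adjusted p = 0.331 with an estimated correlation. Of 15 stem and progenitor regulators 7 fell, among them Myb (-2.49 ± 0.64), Erg (-3.18 ± 0.64) and Hes1 (-1.87 ± 0.40), with camera adjusted p = 0.00305, and adjusted p = 0.409 with an estimated correlation. In haem synthesis 6 of 14 rose, among them Alas2 (2.14 ± 0.47), Slc25a37 (1.78 ± 0.16) and Alad (1.04 ± 0.14), with camera adjusted p = 5.98e-05, and adjusted p = 0.348 with an estimated correlation. In the membrane list 10 of 19 rose, including Epb4.1 (1.60 ± 0.15) and Gypc (1.34 ± 0.18), and Icam4 fell, with camera adjusted p = 8.51e-06, and adjusted p = 0.331 with an estimated correlation. Of 6 globin genes 3 rose, among them the copies Hbb-b1 and Hbb-bs, with camera adjusted p = 0.00208, and adjusted p = 0.331 with an estimated correlation. In autophagy and organelle clearance 7 of 18 rose, such as Bnip3l (1.25 ± 0.20), and Trim58 fell (-2.67 ± 0.73), with camera adjusted p = 0.00848, and adjusted p = 0.331 with an estimated correlation.

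The remaining lists named so far did not pass camera's test between 13 h and 24 h. Of erythroid transcription factors 3 of 15 rose, namely Klf3 (1.58 ± 0.15), Nfe2 (1.27 ± 0.27) and Tal1 (0.59 ± 0.17), with adjusted p = 0.0798. Of iron genes 3 of 13 rose and 1 fell (0.323), of mitosis genes 3 of 19 rose and 1 fell (0.244), of megakaryocyte markers 1 of 12 rose and 4 fell (0.167), and of mast cell and basophil markers 2 of 9 fell (0.178). Adjusted over the list alone, 20 S phase genes and 22 ribosome biogenesis genes fell, and 9 haem, 13 membrane, 5 globin and 4 iron genes rose, with the other counts unchanged.

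Of the elements, 1858 rose and 2749 fell between 13 h and 24 h, and the balance depends on the scaling, with 569 and 1883 under gene-body scaling and 764 and 2906 under total counts. At intergenic sites 194 rose and 1126 fell, and on the strand antisense to a gene 41 rose and 394 fell. The largest increases lay at the start of Slc4a1 (chromosome 11, 102224550 to 102227451, mm9), from 1.84 ± 0.335 to 94.6 ± 22.2 CPM (5.68 ± 0.49), and at the start of the neighbouring noncoding gene Bloodlinc (chromosome 11, 102235400 to 102238601; 3.68 ± 0.48). Others lay between Ankrd6 and Rragd (4.51 ± 0.87), inside Rragd (chromosome 4, 33092950 to 33094201; 3.40 ± 0.64) and between Mt1 and Nup93 (chromosome 8, 96706200 to 96707551; 3.90 ± 0.43). Elements inside Gas2l3, Angpt1 and Pde4d, between Mmd and Tmem100, and between Myc and Pvt1 went from 0.281, 0.276, 0.26, 0.267 and 0.255 CPM to 0.

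The 13 h and 24 h libraries lie in different runs of title numbers, and with a block for the run 59 genes (22 higher, 37 lower) and 1016 elements passed edgeR's test, while 3343 of the 3349 genes and 4598 of the 4607 elements kept their sign. Of the genes named for this comparison Spry4, Erv3, Fgf15, Plk3, Slc25a37 and Epb4.1 kept their call under that block. Without the expression filter Alas2, Kit, Myb and Erg lost theirs. Without 13 h replicate 2 the called genes were 1883, and without 24 h replicate 2 they were 1233, with Alas2 (edgeR adjusted p = 0.0666 and 0.0651) and Hbb-b1 (0.0702 and 0.0694) no longer called. Tal1 lost its call without 13 h replicate 1 (edgeR adjusted p = 0.103), 13 h replicate 2 (0.0946) or 24 h replicate 1 (0.127), and Trim58 without any 1 of the 4 libraries (from 0.0533 without 13 h replicate 1 to 0.158 without 24 h replicate 2). Hspa12a (edgeR adjusted p = 0.065), Dpep1 (0.0776), Kcng3 (0.165) and Myb (0.133) were not called without 24 h replicate 2 either. Called elements were 2332, 2114, 2931 and 651 without 13 h replicate 1, 13 h replicate 2, 24 h replicate 1 and 24 h replicate 2.

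The study concerns regulatory elements that are active for a short time while genes are silenced, and 446 elements from 431 peaks were transient by the definition used here. They rose by a median of 2.24 at 13 h and changed by a median of -2.10 from there to 24 h, which left a median of 0.19 against 0 h. Of these 118 were still higher than at 0 h, 301 were not called and 27 were lower. They made up 10.99% of the 4059 elements activated at 13 h, and 388 were distal to listed starts. By location 193 were intergenic, 124 antisense to a gene, 77 in the sense direction inside a gene and 52 at a start. The authors' cluster 7 held 288 of them (64.6%), and since it comes from the authors' table of these samples, and how it was made is not stated, it is not taken as independent evidence.

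The transient elements with the largest increase lay at the start of Gng13 (0.0167 ± 0.0157, 8.89 ± 1.97 and 1.73 ± 0.468 CPM at 0 h, 13 h and 24 h), near Wnt4 (chromosome 4, 136734450 to 136736951, mm9; 7.17 ± 0.72, then -4.42 ± 0.68), inside Ece1 (chromosome 4, 137482200 to 137484551; 7.08 ± 0.63, then -1.87 ± 0.52), between Hoxb1 and Skap1 (chromosome 11, 96257650 to 96260301; 6.91 ± 0.63, then -2.71 ± 0.55) and inside Aldh3b3 (chromosome 19, 3966150 to 3968351; 7.41 ± 0.74, then -2.24 ± 0.59). With the run as a block none of these 5 falls was called, and the one inside Aldh3b3 reversed (0.99, edgeR adjusted p = 0.72). The falls inside Aldh3b3 (from 0.0584 without 24 h replicate 1 to 0.205 without 24 h replicate 2) and Ece1 (from 0.0509 without 13 h replicate 2 to 0.235 without 13 h replicate 1) lost their calls in edgeR without any 1 of the 13 h and 24 h libraries. Those at Gng13 (0.0856) and between Hoxb1 and Skap1 (0.0912) lost theirs without 24 h replicate 2, and Gng13 also without 13 h replicate 1 (0.0519). An element between Cercam and Mir219a-2 went from 0.0241 ± 0.0271 over 4.47 ± 0.903 to 0.884 ± 0.154 CPM. At 0 h those near Sstr5, inside Dok7, near Mir193b and antisense in Ppargc1b held 0 CPM and reached 2.08, 1.02, 0.759 and 0.729 CPM at 13 h. With the run as a block the falls of these elements and of the one between Cercam and Mir219a-2 were not called either. Among genes 133 of the 1464 activated at 13 h were transient (9.09%), including Dok7 (7.25 ± 0.60, then -3.40 ± 0.55), the granulocyte colony factor receptor Csf3r (4.01 ± 0.55, then -2.55 ± 0.57) and the platelet glycoprotein Gp1ba (2.04 ± 0.42, then -2.24 ± 0.48). Of these genes 39 were still higher at 24 h than at 0 h, 83 were not called and 11 were lower.

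Simulated unchanged libraries with the same controls gave a mean of 0.05 transient genes and 0 transient elements. That simulation held no difference between runs, though the 13 h and 24 h libraries lie in different runs. With the run as a block 58 elements and 3 genes passed as transient, and the median fall of the 446 elements from 13 h to 24 h was then -1.70 with 439 still falling. Without 13 h replicate 1, 13 h replicate 2, 24 h replicate 1 and 24 h replicate 2 the transient elements were 169, 218, 254 and 45, and the transient genes were 73 and 82 without 13 h replicates 1 and 2 and 37 without 24 h replicate 2. Csf3r was no longer called in its fall without 13 h replicate 1 (edgeR adjusted p = 0.0549), 24 h replicate 1 (0.0502) or 24 h replicate 2 (0.0838).

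Kit showed this on 1 strand of its own locus. At 13 h, when Kit itself was falling, 3 antisense elements inside the gene rose, at chromosome 5, 75974250 to 75976501 (mm9) from 3.27 ± 0.785 to 13.8 ± 1.05 CPM (2.08 ± 0.33), at chromosome 5, 76003500 to 76005151 (3.12 ± 0.57) and at chromosome 5, 76018300 to 76021301 from 0.155 ± 0.105 to 4.53 ± 0.684 CPM (4.92 ± 0.60). Of these the element nearest the start fell back to 2.46 ± 0.939 CPM at 24 h (-2.48 ± 0.39), and the element farthest from it was still higher at 24 h than at 0 h (3.24 ± 0.60). The middle one had 1.54 ± 0.59 at 24 h, a call lost without any 1 of the 0 h, 13 h or 24 h libraries (edgeR adjusted p from 0.0545 without 0 h replicate 1 to 0.164 without 24 h replicate 1), with either block, and in other settings. The sense strand of the same 3 peaks fell, for example from 57.7 ± 13.3 over 19.3 ± 3.60 to 6.32 ± 2.75 CPM (-1.58 ± 0.28 and -3.19 ± 0.31 against 0 h). In all 14 elements within 100 kb of the Kit start or inside the gene were tested, of which 3 rose and 6 fell at 13 h, and 2 rose and 9 fell at 24 h.

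**Figure D3:**
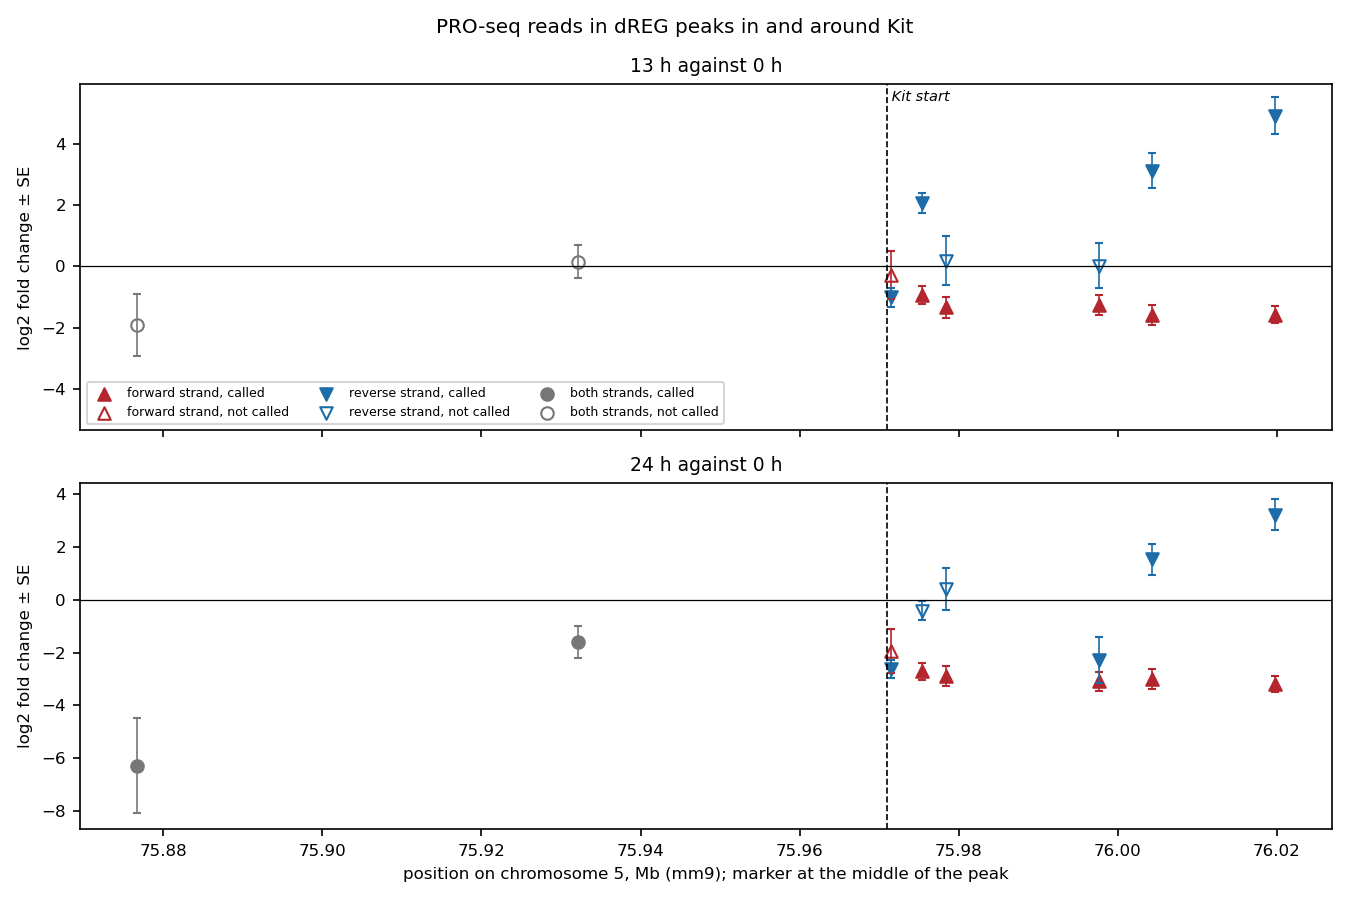
Log2 fold change ± SE of PRO-seq reads in dREG peaks (markers at peak middles) against position on chromosome 5 in Mb (mm9), for 13 h (top) and 24 h (bottom) against 0 h, with filled markers past the test and the start of Kit dashed. The 3 antisense elements inside Kit at 2.08, 3.12 and 4.92 rose at 13 h while sense elements fell.

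Around Gata2 8 of 14 elements fell at 13 h and 11 at 24 h, and 0 rose. An intergenic element at chromosome 6, 88094250 to 88096001 (mm9) fell from 16.2 ± 5.84 to 0.511 ± 0.192 CPM (-4.97 ± 0.46), another at chromosome 6, 88139100 to 88140951 from 77.7 ± 17.4 to 21.3 ± 2.33 CPM (-1.87 ± 0.24), and the element inside Gata2 at chromosome 6, 88151350 to 88157701 from 534 ± 208 to 66.4 ± 28.5 CPM (-3.01 ± 0.51). Around Myc 2 of 6 elements fell at 13 h and 4 at 24 h, among them an element in Pvt1 at chromosome 15, 61870100 to 61871951 (-2.26 ± 0.51 at 13 h and -3.57 ± 0.60 at 24 h). The start of Myc itself had 285 ± 53.6, 187 ± 28.0 and 62.8 ± 27.0 CPM at 0 h, 13 h and 24 h.

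Genes that were at least 2-fold lower at 24 h were less often near an element activated at 13 h than matched genes that did not change. Of 2488 such genes with a known start 845 (34.0%) had an activated distal element within 100 kb, against 41.8% (40.1% to 43.5%) in matched draws from 4109 control genes. With elements outside every gene body the gap was smaller, at 16.4% against 21.2%. The share of draws at least as far off was 0.0001, the smallest they can give. Genes that rose at least 2-fold at 24 h had one more often, with 1127 of 1922 (58.6%) against 43.2% (41.4% to 45.2%), where the share of draws at least as far off was again 0.0001, the smallest they can give. For transient elements the shares were 7.40% against 8.50% near genes that fell (share of draws 0.0367) and 11.3% against 9.56% near genes that rose (share of draws 0.0073). Elements inside a gene can hold reads of that gene's own transcription, so a rising gene may raise them by itself. Genes that rose were not compared on elements outside gene bodies alone, so their excess may be partly built in.

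Genes that fell and had an activated element nearby had gone through a smaller part of their fall by 13 h. The ratio of the 13 h to the 24 h log2 fold change had a median of 0.524 in the 845 genes with such an element and 0.573 in the 1643 without (difference -0.0496, permutation p = 0.00016). These permutations and the matched draws above treat genes as independent, though neighbours share elements and all genes share the libraries. Neither measures the spread between libraries. The 24 h falls of the genes with and without an element differed too (medians -1.93 and -2.13), and within strata of that fall and of the number of elements the difference was -0.028 (permutation p = 0.0002). For a transient element the difference was -0.073 over 184 genes with one (permutation p = 0.0007). With the run as a block the difference was -0.0263 (permutation p = 0.0228), and without 13 h replicate 2 it was -0.0157 (permutation p = 0.252).

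G1E-ER4 at 0 h against G1E asks how the lines differ before GATA1 is switched on. Srxn1, an antioxidant enzyme (start at chromosome 2, 151931260, mm9), was at 30.2 ± 5.23 CPM in G1E-ER4 (n = 3) and held 0 reads in G1E (n = 2), at least 1421-fold lower. The Wnt secretion factor Wls went the other way, at 119 ± 11.7 CPM in G1E and 0.0329 ± 0.0196 CPM in G1E-ER4 (-11.75 ± 0.29, edgeR adjusted p = 1.61e-08). In all, 1090 genes were higher in G1E-ER4 and 1325 lower. The mitosis, S phase and ribosome biogenesis lists had 0 called members.

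With 0 reads in G1E, Foxd2os was at least 690.5-fold higher in G1E-ER4, the developmental factors Osr2 at least 370.3-fold and Foxa1 at least 249-fold, Zfp449 at least 316-fold, the Notch modifier Lfng at least 207-fold and Tusc1 at least 178-fold. Parm1 was higher by 11.06 ± 0.46. With 0 reads in G1E-ER4 at 0 h, the cadherin Fat1 was at least 1073-fold lower and Plekhf1 at least 327-fold lower. Tbc1d19 was 4750.0-fold lower (95% counting interval 1315 to 39220.0), Bdnf 2772-fold (498 to 109500.0), Lonrf2 2044-fold (699 to 9910.0) and Slamf1 2573-fold (462 to 101600.0). Dnajc27 (-11.71 ± 0.53), Pced1b (-11.09 ± 0.43) and Sytl5 (-10.64 ± 0.42) were lower too.

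In the red cell membrane and cytoskeleton list 9 of 19 were lower in G1E-ER4 at 0 h, among them Epb4.2 (-2.87 ± 0.28) and Slc4a1 (-2.02 ± 0.58), and Dmtn (1.77 ± 0.22) and Ank1 were higher. Adjusted over the list alone 12 were lower and 2 higher, and camera gave adjusted p = 0.167. Of 15 erythroid transcription factors 4 were lower, including Zfpm1 (-1.64 ± 0.34) and Tal1 (-0.75 ± 0.15), and 0 higher (camera adjusted p = 0.951). Of 9 mast cell and basophil markers 4 were higher, among them Ms4a2 (4.38 ± 0.71) and the leukotriene enzyme Alox5 (4.43 ± 0.37), with 0 lower (0.172). Haem synthesis had 1 higher and 1 lower of 14, iron 1 higher and 0 lower of 13, stem and progenitor regulators 1 higher (Fli1, 2.98 ± 0.44) and 1 lower (Lyl1, -0.64 ± 0.17) of 15, autophagy 2 higher and 1 lower of 18, and megakaryocyte markers 1 higher and 2 lower of 12. For each of these camera's adjusted p was 0.951, apart from megakaryocyte markers at 0.749. Globin, mitosis, ribosome biogenesis (0.951 each) and S phase genes (0.897) had 0 called members, and the globin list had a median of -1.25 but a mean of 0.74. Adjusted over the list alone 0 haem genes and 0 autophagy genes were lower and 2 megakaryocyte markers were higher, with the other counts unchanged.

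Kit was at 1007 ± 235 CPM in G1E and 562 ± 76.5 CPM in G1E-ER4 at 0 h (-0.84 ± 0.30, edgeR adjusted p = 0.0876), and it lies in a window of chromosome 5 (70 to 80 Mb, mm9) where the median of 26 genes was -0.53. Tal1 lies at 110 to 120 Mb of chromosome 4, where the median of 50 genes was -0.63, and Zfpm1 at 120 to 130 Mb of chromosome 8, where the median of 66 genes was -0.53. In all 26 of 200 windows of 10 Mb were shifted, 10 higher and 16 lower in G1E-ER4. Within G1E-ER4, 80 of the 200 windows passed the same bound for 24 h against 0 h. On chromosome 4 the windows from 100 to 150 Mb had medians of -0.51, -0.63, -0.55, -0.36 and -0.30, and in the one from 120 to 130 Mb 97.3% of 73 genes were lower. On chromosome 2 those from 160 to 190 Mb had medians of 0.52, 0.57 and 0.61, and on chromosome 1 all 23 genes from 190 to 200 Mb were lower (-0.69). Shifted windows held 990 of 7681 genes and 340 of the genes called between the lines, of which 306 moved with their window. Other windows held 6691 genes and 770.0 called ones, of which 489 moved with theirs, and called genes help set the median of a window.

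**Figure D4:**
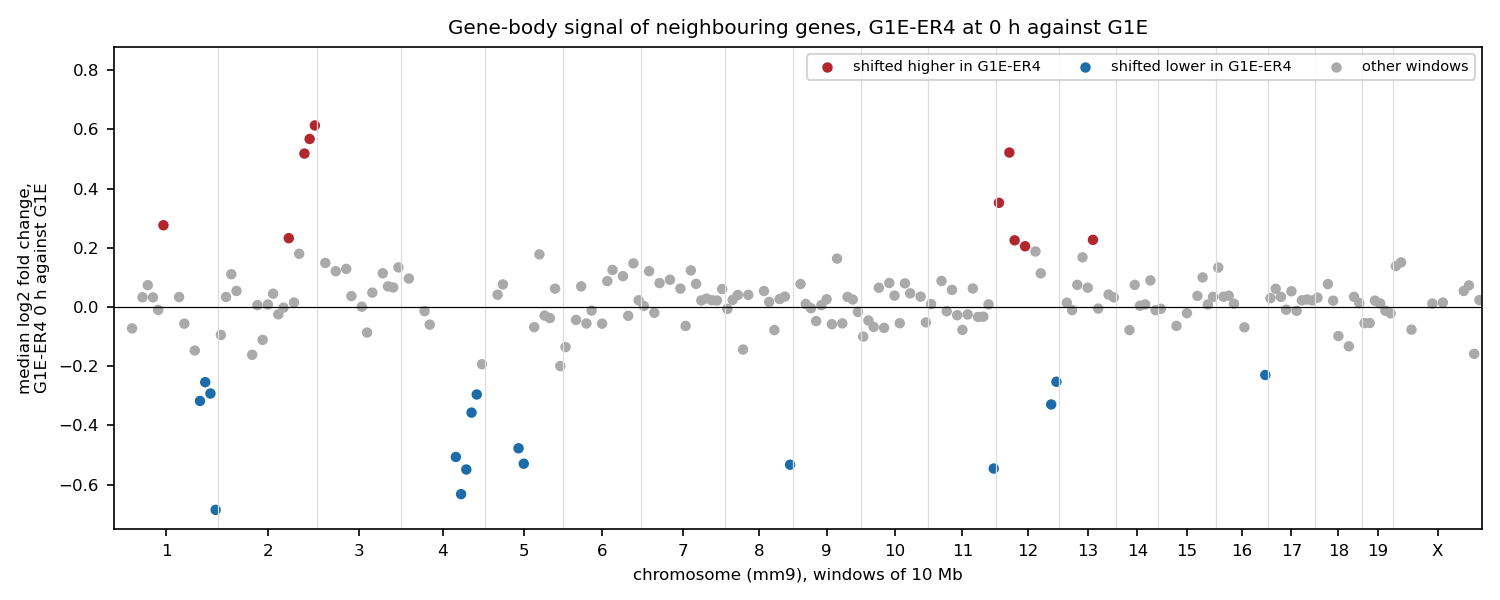
Median log2 fold change of G1E-ER4 at 0 h against G1E in each 10 Mb window with at least 15 genes (points), relative to all genes, along the chromosomes of mm9, with windows past 0.2 coloured. Long stretches of chromosomes 4 and 1 lie lower in G1E-ER4, down to -0.69, and the end of chromosome 2 lies higher, up to 0.61.

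Among elements higher in G1E-ER4 than in G1E, the largest fold changes were at the start of Srxn1 (chromosome 2, 151930450 to 151932651, mm9), with 0 CPM in G1E and 65.1 ± 9.36 CPM in G1E-ER4 at 0 h, followed by the starts of Golim4 (0 and 36.4 ± 3.73 CPM), Tm2d1 (0 and 28.2 ± 5.12 CPM), inside Chsy1 (0 and 25.5 ± 2.75 CPM) and Gna12 (0 and 23.3 ± 4.05 CPM). In the other direction an intergenic element next to Ly6e (chromosome 15, 74759050 to 74765301) had 296 ± 124 CPM in G1E and 0 in G1E-ER4. One between Adam6b and Tmem121 (chromosome 12, 114660650 to 114664701) had 183 ± 45.1 and 0.00630 ± 0.0109 CPM, and elements near Zmiz1, in Dapk1 and at Lincenc1 went from 37.0 ± 7.56, 31.8 ± 6.88 and 79.8 ± 35.7 CPM to 0, 0 and 0.00892 CPM. In all, 2523 elements were higher in G1E-ER4 and 4245 lower, with 2157 of the lower ones intergenic.

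With the run as a block 820 genes passed between the lines, and Fli1 lost its call. Without G1E replicate 1 the called genes were 1145 and the called elements 2420, and Zfpm1 (edgeR adjusted p = 0.0961), Tal1 (0.0768), Slc4a1 (0.846) and Lyl1 (0.283) lost their calls, and without G1E replicate 2 the called genes were 1577 (586 higher, 991 lower). Slc4a1 and Lyl1 also lost theirs with either block (edgeR adjusted p = 0.0787 and 0.0563 by run) and without 0 h replicate 1 (0.0858 and 0.0671), 2 (0.0712 and 0.0631) or 3 (0.0681 and 0.0662).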

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

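No explanation was tested for these values. They are given because genes and elements moved in opposite directions against the same 0 h libraries at the 2 time points, with the difference between the times itself past edgeR's test.

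Among genes 25 were called in opposite directions at 13 h and 24 h, of which 15 rose and then fell below 0 h and 10 fell and then rose above it. Rrm2, a subunit of the enzyme that makes DNA building blocks, had 0.36 ± 0.12 at 13 h and -0.83 ± 0.12 at 24 h (n = 2 each, against n = 3). Klf3, a repressor of the Klf family, had -0.44 ± 0.14 and 1.14 ± 0.13. Among elements 42 were called in opposite directions, 35 that rose and then fell and 7 that fell and then rose. All 25 genes and all 42 elements kept the direction of their change from 13 h to 24 h with the title-number block. Of the genes only Ampd2, Col5a1 and Cpne7, named after their values were seen, were also called in it between 13 h and 24 h (edgeR adjusted p = 0.0479, 0.0479 and 0.0273), while Rrm2 (0.0666) and Klf3 (0.0619) were not.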

How the results depend on the processing

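The alternative that used elements with the authors' regulatory mark was chosen after the data were seen, and the other alternatives were planned. Of the alternatives to the counts and tests of the comparisons, 197 kept the direction and the side of the threshold or stayed within 1.5 times the count, and 31 did not. The causes were not tested, except where a setting by its construction has fewer libraries, fewer degrees of freedom or a stricter threshold.

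A fold threshold of 2 left 3055 genes at 13 h, 5414 at 24 h and 1487 between 13 h and 24 h (403 higher, 1084 lower). With the title-number block, which leaves 2 residual degrees of freedom, 59 genes (22 higher, 37 lower) and 1016 elements (240 higher, 776 lower) passed between 13 h and 24 h, 820 genes passed between the lines, and 58 elements and 3 genes were transient. In that setting the median SE between 13 h and 24 h went from 0.24 to 0.31 over genes, and 3172 genes had an unadjusted edgeR p below the threshold. The element inside Aldh3b3 (chromosome 19, 3966150 to 3968351, mm9), transient without the block, reversed to 0.99 between 13 h and 24 h (edgeR adjusted p = 0.72). A fit with 2 groups gave 1583 genes between 13 h and 24 h and 75 transient genes. Gene-body scaling gave 2452 elements between 13 h and 24 h (569 higher, 1883 lower), and 5626 higher against 4428 lower at 13 h. Total counts gave 641 genes higher and 3082 lower, and 764 elements higher and 2906 lower, between 13 h and 24 h. With an estimated correlation 0 of the 72 camera tests passed, where the preset correlation gave 24 and the other alternatives gave 24 to 28.

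Replicate numbers do not pair the libraries by their labels, and deviations from the group means had r = 0.459 and 0.444 between 0 h and 13 h libraries of the same number but 0.0631 between 0 h replicate 1 and 24 h replicate 1. A block by replicate number gave 4205, 7413 and 2380 genes for 13 h and 24 h against 0 h and for 24 h against 13 h, and 1552 between the lines.

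Leaving out each library in turn gave these ranges, where a lone sample left in a group is assumed to vary like the other groups. Genes ran from 3830.0 to 5753 at 13 h, 6673 to 8410.0 at 24 h, 1233 (without 24 h replicate 2) to 3359 between 13 h and 24 h, and 1145 (without G1E replicate 1) to 2522 between the lines. Elements ran from 7625 (without 13 h replicate 1) to 11963, 13556 to 18806, 651 (without 24 h replicate 2) to 5747, and 2420.0 (without G1E replicate 1) to 7306. Without G1E replicate 2, 1366 elements were higher and 3759 lower between the lines. Transient elements ran from 45 (without 24 h replicate 2) to 667 (without 0 h replicate 1), and transient genes from 37 to 154. The difference in the share of genes near an activated element ran from -9.15 to -6.41 points. The difference in the share of the fall reached at 13 h ran from -0.0775 (without 13 h replicate 1) to -0.0157 (without 13 h replicate 2, permutation p = 0.252).

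Among named genes, lists and elements, 686 alternatives took a called value to the other side of the threshold without changing its sign. In counts simulated from the 0 h levels with the sizes of these libraries 38 of 100 planted 2-fold changes of genes were found at 13 h and 8 of 100 for elements.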

Other observations

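In this part, the test of shuffled gene positions was chosen only after the result was seen, and elements outside gene bodies, a setting fixed beforehand, were used to test an explanation only after their result was seen.

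Of 6 tested granulocyte and monocyte markers, Csf2rb (4.39 ± 0.27) and Csf3r (4.01 ± 0.55) rose at 13 h (camera adjusted p = 0.0501). At 24 h Csf2rb was higher (4.80 ± 0.27; 0.318 for the list), Csf3r fell between the times (-2.55 ± 0.57; 0.628), and in G1E-ER4 at 0 h Csf2rb and Fcgr3 (3.20 ± 0.49) were higher and Itgam (-2.64 ± 0.52) lower than in G1E (0.951). With the run as a block the fall of Csf3r (edgeR adjusted p = 0.391) and the line differences of Csf2rb (0.455) and Itgam (0.082) were not called. The fall of Csf3r was also lost without 13 h replicate 1 (edgeR adjusted p = 0.0549) or 24 h replicate 1 (0.0502) or 2 (0.0838), and the difference of Csf2rb without 0 h replicate 2 (0.0824) or 3 (0.0512), G1E replicate 2 (0.161) or the filter (0.0728). Of 7 lymphocyte markers, Cd4 rose (2.55 ± 0.54) and Cd3g and Lck (-1.43 ± 0.33) fell at 13 h (0.901), 2 rose and 2 fell at 24 h (0.584), Ebf1 rose and Lck fell between the times (0.26), and Cd3g and Lck were lower in G1E-ER4 at 0 h (0.749). Between the times Ebf1 and Lck lost their calls with either block and without 13 h replicate 1 (edgeR adjusted p = 0.14 and 0.17) or 24 h replicate 2 (0.313 and 0.0812), Ebf1 also without 13 h replicate 2 (0.11) or 0 h replicate 3 (0.0542), and Lck without 24 h replicate 1 (0.133). Between the lines Cd3g lost its call by run (edgeR adjusted p = 0.221) and without G1E replicate 1 (0.0606) or 2 (0.119) or 0 h replicate 2 (0.0625) or 3 (0.0506), and Lck without G1E replicate 2 (0.0545). At 13 h Lck lost its call without 13 h replicate 2 (edgeR adjusted p = 0.0562). Of 7 textbook oestrogen receptor targets, Greb1 (1.56 ± 0.48) and Xbp1 (0.88 ± 0.24) rose and Nrip1 (-0.75 ± 0.12) and Rara (-1.30 ± 0.24) fell at 13 h (0.877), Ctsd and Xbp1 rose and Nrip1 and Rara fell at 24 h (0.94), none was called between the times (0.503), and between the lines Esr1 was higher and Igfbp4 lower (0.951). At 13 h Greb1 lost its call without 0 h replicate 1 (edgeR adjusted p = 0.053) or 13 h replicate 2 (0.181), and Xbp1 without 0 h replicate 2 (0.0501) or 3 (0.0581) or 13 h replicate 1 (0.105). At 24 h Xbp1 lost its call without 0 h replicate 2 (edgeR adjusted p = 0.0897) or 3 (0.0964) or 24 h replicate 1 (0.126) or 2 (0.074) and with total counts (0.337), and without 24 h replicate 1 so did Ctsd (0.0876) and Nrip1 (0.091). The call of Igfbp4 was lost with either block (edgeR adjusted p = 0.199 by replicate number, 0.232 by run), without G1E replicate 2 (0.341), 0 h replicate 2 (0.102) or 3 (0.137), or any 13 h or 24 h library, and in other settings.

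Of 11 immediate early genes, Jun rose (2.64 ± 0.43) and Ier2 (-2.98 ± 0.21) and Ier3 (-1.11 ± 0.27) fell at 13 h (camera adjusted p = 0.838), 2 rose and 4 fell at 24 h (0.532), Jund rose and Ier2 fell between the times (0.294), and 0 were called between the lines (0.951). Of 11 heat shock and stress genes, Ddit3 (1.35 ± 0.14) and Sesn2 (0.99 ± 0.24) rose and 5 fell at 13 h, such as Hspd1 (-1.73 ± 0.32) (0.452), 2 rose and 7 fell at 24 h (0.17), 5 fell between the times (0.129), and Trib3 was higher and Sesn2 lower between the lines (0.951). Jund lost its call between the times with either block and without any 1 of the 13 h and 24 h libraries (edgeR adjusted p from 0.0628 without 24 h replicate 2 to 0.188 without 24 h replicate 1), Ier2 without 24 h replicate 2 (0.0548), Ier3 at 13 h without 13 h replicate 1 (0.0845), and Trib3 between the lines without 0 h replicate 1 (0.0855) or G1E replicate 2 (0.238). With the run as a block Ier2 between the times and Trib3 between the lines were not called either. Of 13 housekeeping genes, 6 fell at 13 h, such as Hprt (-0.76 ± 0.14) and Pgk1 (-2.45 ± 0.59) (camera adjusted p = 0.0769). At 24 h 8 fell and B2m rose (1.35 ± 0.19; 0.0727), between the times 3 fell and B2m rose (0.26; not called in edgeR without 13 h replicate 1, adjusted p = 0.0618, or 24 h replicate 2, 0.0972), and 0 were called between the lines (0.951). Adjusted over the list alone, 3 granulocyte and monocyte markers were lower between the lines, 0 immediate early genes rose between the times, 6 stress genes fell at 13 h, and 7 housekeeping genes fell at 13 h and 4 between the times, with the other counts unchanged.

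Transient elements rose at 13 h in runs 1 and 2 and fell by 24 h in run 3, so a difference between runs is a candidate explanation. The 0 h library of run 3 differed from the other 0 h libraries over these elements by a median of -0.208 (SD 0.408). With the run as a block the median from 13 h to 24 h was -1.70. These values are not separate evidence, as both rest on 0 h replicate 3. They show no run difference at 0 h of the size of the fall. The added 0.1 CPM draws the first value towards 0 at elements near 0 CPM at 0 h. Neither value can therefore exclude a run difference at elements that were close to silent at 0 h. The block left 45 of the 446 called. With it the median SE grew from 0.49 to 0.66, the residual degrees of freedom fell from 5 to 2 and the median fall was smaller. Which of these cost the calls was not tested. Under 3 other scalings the highest of the medians was -2.09, so the choice among these scalings does not account for the fall. Over all tested elements the median moved from -0.085 to -0.081 (DESeq2 size factors), -0.172 (gene-body scaling) and -0.246 (total counts). Changes that small could not have brought a median of -2.10 near 0. A larger error in the scaling of the 24 h libraries was therefore not tested.

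Near an activated element, falling genes had reached a smaller share of their fall by 13 h. Reads of the element counted in the gene body may do this. Elements outside every gene body gave -0.0483 (permutation p = 0.00331). Genes with activated elements inside them were not removed from either set, so this value cannot exclude such reads. Where elements and genes came from different runs the differences were -0.0575 (permutation p = 5e-05) and -0.0592 (1e-05), against a shared chance deviation of the same libraries. Within 50 strata of the 24 h fall and the number of elements the difference was -0.028 (permutation p = 0.0002), smaller than without strata. Without 13 h replicate 2 the difference was -0.0157. Elements and 13 h ratios from run 1, which lacks that library, gave -0.0528 over 2273 genes. Those genes came from the fit with all libraries, the elements were chosen without a test, and both were read in the same run. The value from run 1 therefore does not offset the smaller difference.

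Neighbouring genes were shifted together between the lines in 26 windows, where the highest of 1000 shuffles of gene positions gave 10, which argues against chance clustering. Window medians from 2 library pairs with no library in common had r = 0.854 over 200 windows, which argues against a difference between single libraries. With the change at 24 h in other libraries r was 0.0804, which gives no sign that fusion protein activity without estradiol shifted these windows. Medians of 10 Mb windows would hide such activity at single genes, which was not tested. Within G1E-ER4 the change at 24 h passed the 0.2 bound in 80 of the 200 windows. Medians past this bound are therefore not particular to the difference between the lines. Gene positions were not shuffled for the change at 24 h, so how many of the 80 windows chance would give is not known. A difference in DNA copy number between the lines may shift long stretches, and intergenic elements followed genes with r = 0.352 and 0.496 over 167 windows, which lies between the bounds set beforehand, so it cannot be told apart from other causes here.

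Genes higher in G1E-ER4 at 0 h than in G1E and lower at 24 h than at 0 h numbered 440.0, where independent lists would share 334.8, and those lower and then higher numbered 319 against 384.7. Both comparisons use the 0 h libraries, for which simulated unchanged groups gave r = -0.376 and covariance -0.0489 between the fold changes. The data gave r = -0.0644 and covariance -0.1625, so the covariance was more negative than in the simulation but r was less negative. For elements the data gave r = -0.0124 and covariance -0.0507, both less negative than the simulated -0.375 and -0.0921. No conclusion is drawn from these values. Of 117 genes with a transient antisense element 50.4% rose at 24 h and 24.8% fell, against 39.7% and 26.6% of the 2625 genes with any tested antisense element. For sense elements the shares were 30.4% and 17.4% of 69 against 35.2% and 30.8% of 4245, and for elements at starts 41.1% and 21.4% of 56 against 34.3% and 31.3% of 10125.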
